A study of Mus musculus with 2 samples.

How the data were processed

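H3K9ac was measured by chromatin immunoprecipitation and sequencing in embryonic day 12.5 mouse liver, in 2 samples that the labels give as biological replicates 1 and 2 of 1 group, pooled from 120 and 88 embryos. The labels name separate pools for the replicates and 1 strain. Each replicate's deposited file is a list of peaks called from that library's alignments and 1 control file, per the labels and the notes deposited beside them. A further list was called on both libraries together with 2 control files, and the list of replicated peaks was derived by the authors from these 3 lists by a rule that is not given in the sources used here. The aligner, the peak caller, its thresholds and the read depth are not given in the sources used here. The build is mm10, per the labels.

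Each peak in the deposited lists has a fold enrichment over control, which is a linear ratio computed by the authors' peak caller. Each also has a −log10 p and a −log10 q as deposited, and a summit position in bp from its start, also from the authors. The smallest −log10 p in the 4 lists was 2.00 and the smallest −log10 q was 0.313. The fold is the authors' own value for a peak and was used to describe and rank peaks. With no read counts, no interval for a fold could be given, and the intervals for shares are exact binomial (Clopper-Pearson) 95% intervals that cover counting error only. All coordinates lay within the chromosome lengths of the reference assembly.

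Peaks on the assembled chromosomes were used, so 13, 10, 11 and 8 peaks on unplaced or unlocalized sequences were left out of the lists of replicate 1, replicate 2, both together and replicated peaks. Annotation came from GENCODE M21 (comprehensive set) and sequence from GRCm38.p6. There were 132721 annotated starts of 55413 genes of all types, of which 21938 genes were protein-coding. A promoter was 1 kb either side of any annotated start, and a gene had a promoter peak when a peak overlapped it by at least 1 bp. A gene's fold was that of its highest promoter peak. Domains were peaks joined across gaps of up to 1 kb. Distal peaks touched no promoter, and those in a gene body or within 50 kb of its starts were counted for the gene. The CpG ratio is the observed number of CpG over that expected from C and G, within 1 kb either side of the gene's most upstream start. In genes with several starts it may thus describe another window than that of the peak. Genes that share a promoter share its peak, and counting a peak only for the nearest start was tried as an alternative.

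The gene lists, pairs of lists, motifs, tests, settings and most alternatives were fixed before the data were examined. The 22 lists held erythroid, heme synthesis, fetal hepatocyte, adult hepatocyte metabolism, coagulation and complement, haematopoietic stem and progenitor, megakaryocyte and platelet, myeloid and macrophage, lymphoid, endothelial, mesenchymal with stellate and mesothelial, neural, skeletal and cardiac muscle, other endoderm with kidney and skin epithelium, germ cell, housekeeping, proliferation, ribosomal protein, olfactory receptor, keratin-associated protein, Hox and imprinted genes. Of 527 listed symbols, 4 matched no protein-coding gene of the annotation (Ahsp, H19, Meg3 and Kcnq1ot1), and C5 was read as Hc. The lists were written from general knowledge of the cell types and not from these libraries.

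The share of each list with a promoter peak was compared with all other protein-coding genes by Fisher's exact test, two-sided, and 8 pairs of lists were compared with each other in the same way. Median fold, median domain width and mean number of distal peaks of the covered members of each list with at least 5 of them were set against 10000 random lists of the same size drawn from genes with a promoter peak. The two-sided permutation p can be no smaller than 0.0002. Motifs were searched on both strands within 100 bp of distal summits and in windows of the same width 2 kb to the side that touched no peak of the jointly called list, with an exact McNemar test. For 10 of the motifs the reversed sequence served as a control of equal composition. Of 17416 distal peaks, 14948 had a usable flank and 2468 were left out. The p-values of each family were Benjamini-Hochberg adjusted, with a threshold of 0.05. The replicates are 1 library each of 1 group, so no test between them was made, and overlap was set beside the mean of 20 random placements of the peaks on the same chromosomes.

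The genes named in the text follow a fixed rule. In each list they are the 4 members of highest fold with a peak, and up to 3 members, in alphabetical order, with no peak in either replicate's own list. Genome-wide they are the 10 genes of highest fold, the 10 with the widest domains, and for each replicate the 5 of highest fold with no promoter peak in the other's list. The 10 regions described were fixed with 50 kb on each side. Members named beyond that rule, such as Tfrc, Tal1, Apoe, Hnf4a, Afp and the genes named with counts of distal peaks, were chosen after their values were seen.

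The alternatives were promoters of 500 bp and 2.5 kb, peaks of −log10 q of at least 2, the jointly called list, each replicate's own list, a summit inside the promoter, lists matched on decile of promoter CpG ratio, a joining gap of 3 kb, a search distance of 20 kb, lists matched on neighbouring starts, motif windows of 250 bp either side and control windows of like GC content. For the replicates they were overlap over 50% of the length, lists of equal length, and −log10 p in place of fold. Added after the data were seen were the basic transcript set, the nearest start alone, lists matched on the length of the searched region, the counting of each distal peak 1 time in a list, and, for the X chromosome, autosomal genes of like CpG ratio, the removal of mostly repeated promoters, and both together. A promoter was called mostly repeated when at least 50% of its words of 50 bases occur more than 1 time in the assembled chromosomes. For this the promoter was also taken at the gene's most upstream start alone. The read length is not given in the sources used here.

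The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, numba 0.67.0 and samtools 1.23.1. The main steps were tested on simulated data with known answers, but the pairs of lists, the windows of like GC content, the matched draws for the X chromosome, the choice of the nearest start and the comparison of motifs with their reversed sequences were not. With the 21938 real genes, Fisher's exact test recovered 96% of 50 simulated lists of 30 genes with 90% against 58% covered, and called 6% of lists with no difference. The permutation test of a median recovered 58% of 50 lists whose values were 2 times higher, and 0% of lists with no difference, both with and without CpG matching. That of a mean recovered 36% and 0%, so true differences of that size were missed often. All of 1000 peaks placed on starts were assigned (100%), and a GATA sequence planted in 10% of 5000 windows was called. The count of each distal peak 1 time recovered all of 50 lists of 30 genes with 10 more distal peaks per gene, and called 0% of lists whose genes shared 1 set of peaks higher. All of 1000 peaks overlapped by 1 bp and 1000 pairs of peaks 500 bp apart were found and joined, and no peaks that only touched or lay beyond the joining gap. A share of 50% of X-linked against 58% of autosomal genes was called in all of 50 simulations (100%), and equal shares in 2%. The counting of repeated words was checked on random sequence.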

Results

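Acetylation of lysine 9 on histone H3 (H3K9ac), a mark found at the starts of active genes and at active enhancers, was mapped by chromatin immunoprecipitation and sequencing in liver from mouse embryos at embryonic day 12.5. At that age the liver is the main site of red blood cell formation, and hepatocytes are still immature. There were 2 biological replicates of 1 group, both of strain B6NCrl with both sexes pooled. Replicate 1 was made from 120 embryos and replicate 2 from 88. On the assembled chromosomes, replicate 1 had 62747 peaks covering 36.4 Mb, with a median width of 289 bp and a median fold enrichment over control of 3.68. Replicate 2 had 79743 peaks covering 44.5 Mb, with a median width of 266 bp and a median fold of 3.42. A list called on both libraries together held 75363 peaks, and the authors' list of replicated peaks held 36086, which covered 40.5 Mb with a median width of 723 bp and a median fold of 4.86. The gene results rest on the replicated list. Read depth is unknown, because the values are peak scores and no read counts were used here. All coordinates are on GRCm38 (mm10).

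The first comparison asked how far the replicates gave the same regions. The coproporphyrinogen oxidase gene Cpox, which encodes an enzyme of heme synthesis, carried the promoter peak of highest fold in the replicated list, and its highest promoter peak had 56.5 in replicate 1 and 61.4 in replicate 2. The erythroid regulator genes Lmo2 (46.5 and 47.6) and Klf1 (38.8 and 43.2) were also close between replicates. The astrocyte gene Gfap was not, with 4.11 in replicate 1 and 25.2 in replicate 2 for its highest promoter peak in each. Its replicated peak had a fold of 28.9, above both, and lay on chromosome 11 from 102894229 to 102896860. The values of the replicates need not be of the same peak, so they do not show that the replicates differ at this gene. Among peaks of replicate 1, 62.5% (95% exact binomial interval 62.1 to 62.9) were overlapped by at least 1 bp in replicate 2, against 3.76% for random placement. Among peaks of replicate 2, 45.0% (44.6 to 45.3) were overlapped in replicate 1, against 2.97%. The overlap was 100% in the top decile by fold of each list, and 34.2% and 16.8% in the lowest decile of replicates 1 and 2. Of the replicated regions, 30564 (84.7%) had a peak in both replicates' own lists. Across these regions, Spearman's rho of the fold was 0.853 and Pearson's r of the log2 fold was 0.913, and the log2 fold of replicate 2 minus that of replicate 1 had a median of 0.16 (SD 0.47). No region had identical values in both lists. These correlations are across regions of 1 pair of libraries, and regions are not replicates, so no p-value was computed.

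**Figure D1:**
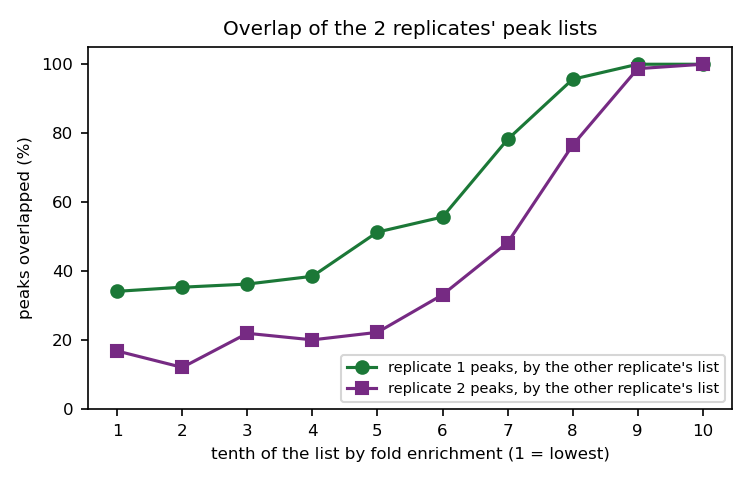
Share of each replicate's peaks (vertical axis, percent) overlapped by at least 1 bp in the other replicate's list, by decile of fold enrichment within the list (horizontal axis, lowest to highest). Circles show replicate 1, from 34.2% in the lowest decile to 100% in the highest, and squares show replicate 2, from 16.8% to 100% with its lowest value, 12.1%, in the second decile.

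Protein-coding genes with a promoter peak in only 1 replicate's list were few. There were 475 for replicate 1 and 921 for replicate 2, against 12687 in both. The highest fold among those of replicate 1 was at the predicted gene Gm30191, with 18.9. Those of replicate 2 were led by Myh7b, a myosin heavy chain gene (14.9), Tmem88b, a transmembrane protein gene (14.2), and Nanos3, a germ cell gene (7.42). All 4 genes nevertheless had a peak in the replicated list, with folds of 18.3, 16.8, 13.3 and 9.20. The next genes of replicate 1, Ablim3, Vgf, Entpd3 and Abcb1b, had folds of 5.44 to 5.69. The replicated list was not the plain intersection of the replicates. In 5722 of its regions (15.9%), at least 1 replicate had no peak whose overlap reached 50% of the region's or of that peak's length. Their median fold was 3.30, against 5.84 for the rest.

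The next question was where the mark lay among gene promoters, taken as 1 kb either side of any annotated start. Among protein-coding genes, after Cpox with a fold of 68.2, the highest promoter peaks lay at Sfpq, a splicing factor gene (66.1), Actg1, which encodes a cytoplasmic actin (64.3), Ubtf, a ribosomal RNA transcription factor gene (64.3), and Wdr26, a ubiquitin ligase component gene (63.6). Gclm, of glutathione synthesis, had 63.6, Tmem131 had 63.6, and Top1, the topoisomerase gene, had 62.1. The kinase gene Hipk2 and the thromboxane synthase gene Tbxas1 shared 1 peak of 63.5 on chromosome 6 from 38871610 to 38877805. Of the replicated peaks, 18670 of 36086 (51.7%, 95% exact interval 51.2 to 52.3) lay at a promoter, against 9.14% for random placement. They had a median fold of 10.3 and a median width of 1206 bp, and distal peaks had 3.81 and 500.5 bp. A promoter peak was found for 12792 of 21938 protein-coding genes (58.3%, interval 57.7 to 59.0), 60.0% with replicate 1's own list and 62.0% with replicate 2's. It was found for 30.7% of antisense RNA genes, 11.99% of lincRNA genes and 1.85% of processed pseudogenes. The share of protein-coding genes went from 4.28% in the lowest decile of promoter CpG ratio (observed over expected CpG) to 94.9% in the highest, and the median ratio was 0.616 in genes with a peak and 0.196 in genes without. The share of peaks at a promoter depended on the list, and was 35.1% with the list called on both libraries together.

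Genes of red blood cells carried the mark almost without exception. Of 39 erythroid genes with an annotated start, 38 had a promoter peak (97.4%, interval 86.5 to 99.9), against 58.2% of other protein-coding genes. Among them were Lmo2 (fold 52.0), Klf1 (49.2), the glycophorin gene Gypc (45.8), the spectrin gene Sptb (45.4), the transferrin receptor gene Tfrc (42.7), the anion exchanger gene Slc4a1 (39.9), Tal1 (39.2) and Gata1 (19.3). The exception was Slc25a37, which encodes the mitochondrial iron importer and had no promoter peak in either replicate's list. All of the 50-base words around its most upstream start occurred more than 1 time in the assembled genome (100%). Reads there may thus have no single place. All 9 genes of the heme synthesis list had a peak, from Uros (20.7) to Hmbs (52.3) and Cpox (68.2). Both lists stood above other genes by Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over 22 lists, with adjusted p = 1.13e-07 for erythroid genes and 0.0190 for heme synthesis. The heme synthesis call was lost in 2 of 10 alternatives, when the summit had to lie in the promoter (20.4 percentage points above other genes) or a peak counted only for the nearest start (24.3 points), with adjusted p of 0.00480 to 0.367 over the alternatives (exact tests and 1 permutation test). Genes are not replicates, so each such p describes these 2 libraries only.

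The lists of other blood lineages held between 16.7% and 76.7% covered genes. Of 30 genes of haematopoietic stem and progenitor cells, 23 had a peak (76.7%, adjusted exact p = 0.0552). They included the transcription factor genes Ikzf1 (38.9), Lyl1 (36.7), Runx1 (30.3) and Myb (19.8), and the receptor gene Kit (10.2). Hoxa9 and the surface antigen gene Cd48 had none in the replicated list or in either replicate's own. Of 20 megakaryocyte and platelet genes, 14 had a peak (70.0%, adjusted exact p = 0.384), led by the integrin gene Itga2b (13.3), the platelet glycoprotein gene Gp9 (12.9) and Rab27b (12.6). The peak assigned to Gp9 ended upstream of that gene. Against CpG-matched lists, with a random median of 40%, the megakaryocyte share was higher (adjusted permutation p = 0.0116, range with the exact tests 0.0116 to 0.859 over the alternatives). Of 30 myeloid and macrophage genes, 8 had a peak (26.7%, adjusted exact p = 0.000952), led by the proteinase 3 gene Prtn3 (6.48) and Mafb (4.88), and the macrophage genes Adgre1, C1qa and C1qc had none. Of 30 lymphoid genes, 5 had a peak (16.7%, adjusted exact p = 1.22e-05). These were led by the surrogate light chain gene Vpreb1 (27.5), Foxp3 (17.1), the T cell kinase gene Lck (11.8) and Tcf7 (7.97). Most of the peak assigned to Vpreb1, on chromosome 16 from 16870232 to 16872014, lay upstream of that gene. The progenitor list was above other genes with replicate 2's own list (adjusted exact p = 0.00632) and the jointly called list (0.00343, range with the permutation test 0.00343 to 0.159 over the alternatives). The myeloid call was lost with that list (adjusted exact p = 0.0506) and against CpG-matched lists (adjusted permutation p = 0.705, range 7.13e-05 to 0.705), and the lymphoid call with replicate 1's list (0.0527, range 2.68e-07 to 0.0527).

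Genes of early hepatocytes and of the adult liver parted. Of 41 fetal hepatocyte genes, 29 had a promoter peak (70.7%, interval 54.5 to 83.9), and of 40 genes of adult hepatocyte metabolism, 6 had 1 (15%, interval 5.71 to 29.8). The fetal genes with a peak included the lipid transfer protein gene Mttp (18.3), the apolipoprotein genes Apoh (14.7), Apoe (8.22) and Apoa1 (8.04), the progenitor marker Dlk1 (9.96), and the transcription factor genes Prox1 (7.50), Cebpa (7.10) and Hnf4a (4.77). The peak assigned to Foxa3 (35.5) began upstream of that gene, on chromosome 7 from 19024329 to 19026244. The serum albumin gene Alb had no promoter peak in the replicated list or in either replicate's own, nor did the urea cycle gene Cps1 or the bile acid receptor gene Nr1h4, and the alpha-fetoprotein gene Afp had 1 of fold 3.70 in replicate 1's list and none in replicate 2's or the replicated list. From 50 kb before Alb to 50 kb after Afp there were 0 replicated peaks. The adult genes with a peak were Glul (29.4) and Gls2 (10.5) of glutamine metabolism, the urea cycle gene Ass1 (7.15), the sterol hydroxylase gene Cyp27a1 (7.11), Car3 (4.13) and Hpd (3.39). The bile salt pump gene Abcb11, Aldh1a1 and Aox3 had none. Also without a peak were Cyp2c29, Mup20 and Sult2a1, whose promoters were mostly repeated (85.0%, 78.6% and 70.4% of 50-base words). The 2 shares differed by 55.7 percentage points (Fisher's exact test, adjusted p = 1.14e-06 over 8 pairs of lists). This comparison was not matched on promoter CpG, and the random medians of CpG-matched lists, given below, also differ. Against other genes, the adult list was lower (adjusted exact p = 1.19e-07) and the fetal list did not pass the threshold (adjusted p = 0.140). Against random lists matched on promoter CpG, the fetal list was above the random median of 48.8% (permutation test, adjusted p = 0.00165, range 0.00165 to 0.553 over the alternatives), and the adult list, with a random median of 25%, no longer passed the threshold (0.159, range 1.77e-08 to 0.159). The fetal list was also above other genes with replicate 1's (adjusted p = 0.00342), replicate 2's (0.00309) and the jointly called list (0.00475) by Fisher's exact test. Of 29 coagulation and complement genes, most of them made by hepatocytes, 11 had a peak (37.9%, adjusted exact p = 0.0501), led by the protein S gene Pros1 (13.2) and the prothrombin gene F2 (6.01). That list was lower than other genes with promoters of 500 bp (adjusted exact p = 0.0190, range 0.0190 to 0.471) and with the basic transcript set (0.0202). Against CpG-matched lists its share lay 17.2 percentage points above the random median (adjusted permutation p = 0.0869).

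**Figure D2:**
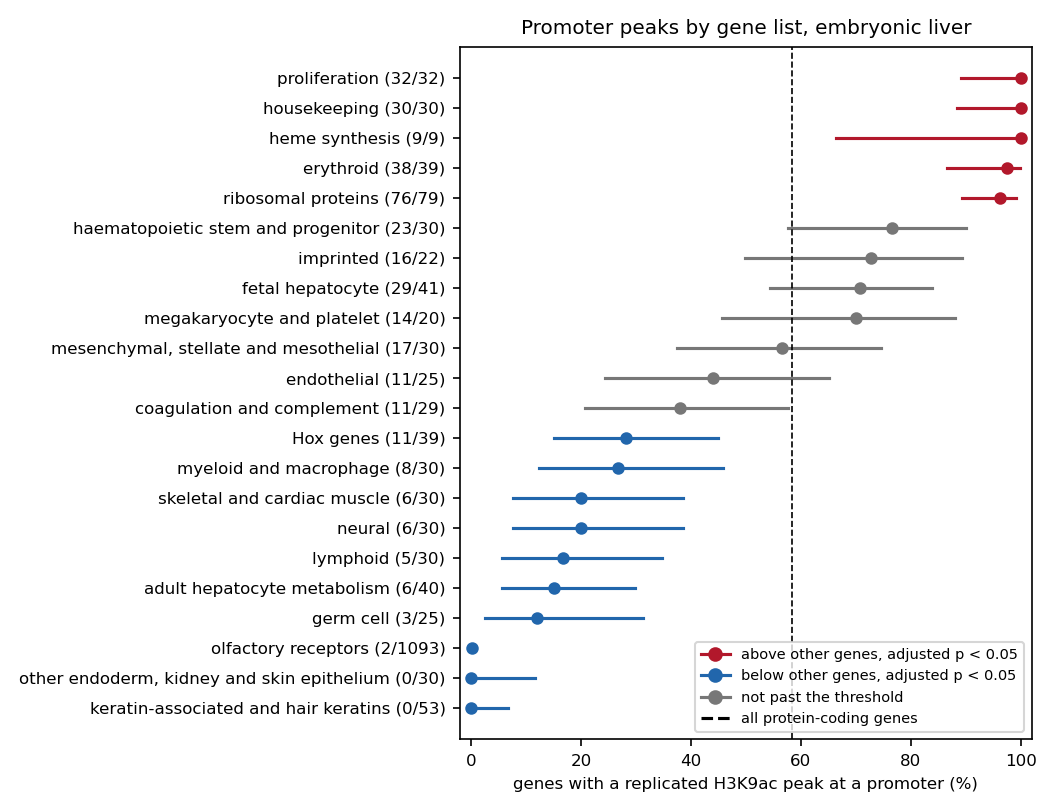
Share of genes in each of 22 lists with a replicated peak at a promoter (horizontal axis, percent), with exact 95% binomial intervals as bars and the number of genes in brackets. Red marks the 5 lists above other genes, blue the 10 below, grey the lists not past the threshold, and the dashed line all protein-coding genes (58.3%).

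Genes of other cell types in the liver, and of other organs, were covered in part or not at all. Of 25 endothelial genes, 11 had a peak (44.0%, adjusted exact p = 0.184), led by Egfl7 (8.25), Eng (6.66) and the VEGF receptor gene Kdr (6.40). Of 30 mesenchymal, stellate and mesothelial genes, 17 had a peak (56.7%, adjusted exact p = 0.855), led by Reln (24.5), Podxl (14.8) and Gata6 (13.4). Shares were lower than in other genes for the neural list (6 of 30, 20.0%, adjusted exact p = 4.23e-05) and for skeletal and cardiac muscle (6 of 30, 20.0%, adjusted p = 4.23e-05). They were also lower for germ cells (3 of 25, 12%, adjusted exact p = 8.66e-06) and for other endoderm, kidney and skin epithelium (0 of 30, upper limit 11.6%, adjusted p = 2.13e-11). The neural genes with a peak were led by Gfap (28.9), Elavl3 (5.002) and Slc17a7 (4.997), the muscle genes by the creatine kinase gene Ckm (9.54), and the germ cell genes by Gdf9 (23.9). The peak assigned to Ckm ended upstream of that gene, on chromosome 7 from 19403412 to 19404169, and most of that assigned to Gdf9 lay upstream. None of the 53 keratin-associated protein genes had a peak (upper limit 6.72%, adjusted exact p = 7.33e-20), and 2 of 1093 olfactory receptor genes had 1 (0.183%, interval 0.0222 to 0.659), Olfr56 (12.2) and Olfr575 (3.201). The exact p for the olfactory receptors lay below the smallest number the software can hold. By contrast, all 30 housekeeping genes had a peak (adjusted exact p = 3.84e-07), among them Ywhaz (57.4) and Actb (54.4), and so did all 32 proliferation genes (adjusted p = 1.3e-07), among them the cyclin genes Ccna2 (50.5) and Ccnb2 (46.9). Of 79 ribosomal protein genes, 76 had a peak (96.2%, adjusted exact p = 8.49e-14), led by Rps19 (58.4) and Rpl11 (44.5). Those without included the paralogs Rpl10l and Rpl39l. Of 39 Hox genes, 11 had a peak (28.2%, adjusted exact p = 0.000393), led by Hoxb2 (7.53), Hoxa4 (6.97) and Hoxa5 (6.97), while Hoxa10, Hoxa11 and Hoxa13 had none. Of 22 imprinted genes, 16 had a peak (72.7%, adjusted exact p = 0.218), led by Impact (23.2), Grb10 (18.8) and Igf2r (15.7), and with the jointly called list their share was higher than in other genes (adjusted exact p = 0.0352, range with the permutation test 0.0352 to 0.735). In all, 5 lists stood above other genes and 10 below.

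Of the 8 pairs of lists compared with each other, 6 passed the threshold. No pair was compared with promoter CpG matched. The erythroid share exceeded the lymphoid share by 80.8 percentage points (adjusted p = 6.36e-12), the neural share by 77.4 points (2.25e-11) and the fetal hepatocyte share by 26.7 points (0.00209), by Fisher's exact test. The fetal hepatocyte share exceeded the neural share by 50.7 points (adjusted exact p = 5.22e-05), and the progenitor share the lymphoid share by 60.0 points (1.18e-05). The myeloid and lymphoid lists differed by 10 points (adjusted exact p = 0.532) and the endothelial and neural lists by 24.0 points (0.0913). The difference between erythroid and fetal hepatocyte genes was lost in 3 of 9 alternatives. It was 14.5 points with replicate 1's list, and 12.1 points with replicate 2's list or the list called on both libraries (adjusted exact p of 0.000946 to 0.146 over the alternatives). The endothelial and neural lists differed in 3 alternatives, by up to 28.0 points (adjusted exact p of 0.0432 to 0.326 over the alternatives).

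Among genes with a promoter peak, the height of the peak separated the lists again. The 9 heme synthesis genes had a median fold of 31.3 (permutation test, adjusted p = 0.0326) and the 38 erythroid genes 24.7 (adjusted p = 0.0430), against medians of 19.02 and 19.15 in random lists of the same size. The proliferation (31.1), ribosomal protein (30.2) and housekeeping (28.4) lists were also higher (adjusted permutation p = 0.00072, 0.00072 and 0.00360). The 29 fetal hepatocyte genes had a median of 5.58, below the 95% range of random lists, which was 12.4 to 25.2 (adjusted permutation p = 0.00072). The medians were also lower for coagulation and complement (3.94, adjusted p = 0.00072), endothelial (4.02, 0.00072), muscle (3.74, 0.00120), myeloid (4.16, 0.00257), neural (4.48, 0.00396), megakaryocyte (6.25, 0.00396) and mesenchymal genes (6.59, 0.00425) by the permutation test. Imprinted (6.79, adjusted permutation p = 0.00510), Hox (5.52, 0.00748) and progenitor genes (8.92, 0.0139) were lower too. The 6 adult hepatocyte genes with a peak had 7.13 (permutation test, adjusted p = 0.0525) and the 5 lymphoid genes 11.8 (0.347). An unadjusted p of 0.0002 is the smallest that 10000 permutations can give, and adjusted values of 0.00072 rest on it. With replicate 1's list, the heme synthesis call was lost (adjusted permutation p = 0.0758, range 0.00180 to 0.0758), while the lymphoid list was lower with each replicate's own list (0.000422 and 0.0306, range 0.000422 to 0.485). Against CpG-matched lists the megakaryocyte call was lost (random median 12.5, adjusted permutation p = 0.112, range 0.00660 to 0.112). The adult hepatocyte list was lower with replicate 2's list (adjusted permutation p = 0.0306) and with −log10 q of at least 2 (0.04997, range 0.0306 to 0.191).

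**Figure D3:**
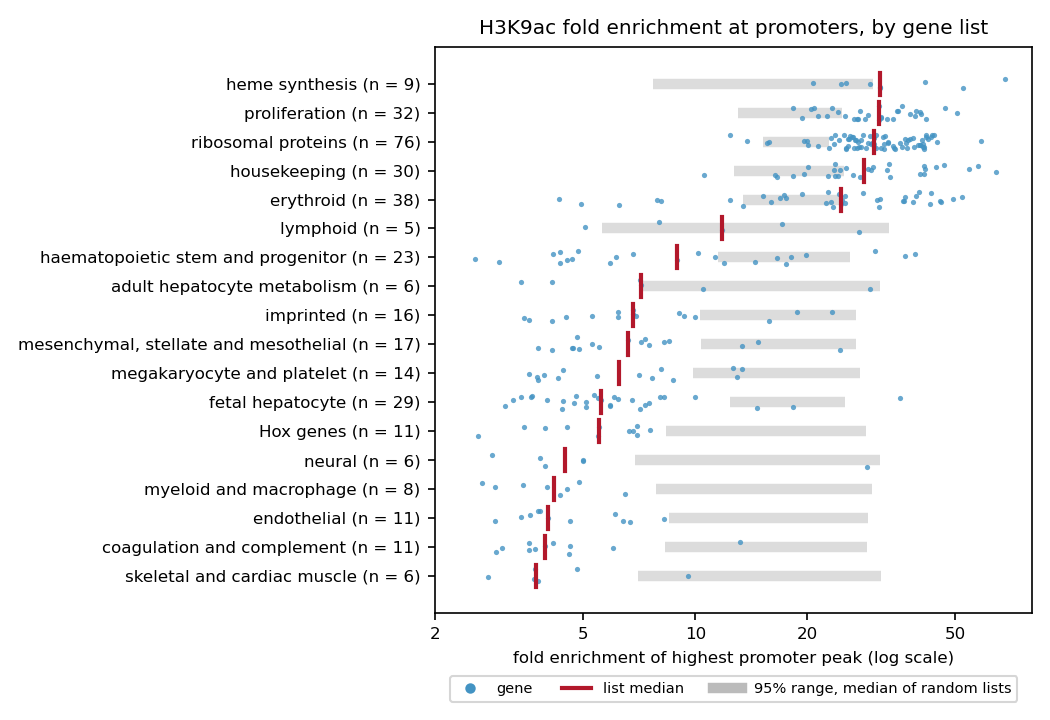
Fold enrichment over control of each gene's highest promoter peak in the replicated list (horizontal axis, log scale), for the 18 lists with at least 5 covered genes. Points are genes, red bars list medians and grey bars the 95% range of the median of random lists, and the median runs from 3.74 in muscle genes to 31.3 in heme synthesis genes.

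Erythroid genes also carried wide domains of the mark, which are replicated peaks joined across gaps of up to 1 kb. The widest domain at any protein-coding gene spanned the alpha-globin genes Hba-a1, Hba-a2 and Hba-x and the neighbouring Nprl3, whose introns hold the alpha-globin enhancers, over 64109 bp. It was followed by the domains at Zfpm1, which encodes the GATA1 cofactor FOG1 (52399 bp), the ankyrin gene Ank1 (38386 bp), Tmcc2 (29881 bp) and the linker histone gene Hist1h1a (29435 bp). The median width was 8807 bp in the 38 erythroid genes and 8012 bp in the 9 heme synthesis genes, against 2284.5 and 2281.5 bp in random lists (permutation test, adjusted p = 0.00072 for both). Members that share a domain, such as the alpha-globin genes, each count in the median. No alternative counted a shared domain 1 time. Among heme synthesis genes, Fech had 16556 bp and Hmbs 12461 bp. Widths were also above random for proliferation (4403 bp, adjusted permutation p = 0.00072), ribosomal protein (3751 bp, 0.00072) and housekeeping genes (3581 bp, 0.00480). They were below for coagulation and complement (452 bp, adjusted permutation p = 0.00072), neural (477 bp, 0.00120), muscle (469.5 bp, 0.00154), endothelial (910 bp, 0.00480) and myeloid genes (1010.5 bp, 0.0299). The permutation test was not passed by progenitor (3202 bp, adjusted p = 0.0664), megakaryocyte (1504.5 bp, 0.108), adult hepatocyte (1495.5 bp, 0.282), fetal hepatocyte (1948 bp, 0.405), mesenchymal (2718 bp, 0.428), imprinted (2702 bp, 0.431), Hox (1870 bp, 0.468) and lymphoid genes (2162 bp, 0.865). With replicate 1's list the myeloid (adjusted permutation p = 0.0918, range 0.0190 to 0.101) and muscle calls (0.119, range 0.00142 to 0.119) were lost and lymphoid genes were narrower (0.000633, range 0.000633 to 0.931). The myeloid call was also lost against CpG-matched lists (random median 1947 bp, adjusted permutation p = 0.101). With replicate 2's list the fetal (0.0286, range 0.0286 to 0.910) and adult hepatocyte lists (0.0122, range 0.0122 to 0.550) were narrower.

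Distal peaks, those at no promoter, gathered around erythroid genes. They were counted as called and not joined across gaps, so pieces of 1 wide domain count singly. How far the counts restate the wide domains of these genes was not tested. In the gene body or within 50 kb of a start, the 38 covered erythroid genes had a mean of 11.3 distal peaks, against 2.82 in random lists (95% range 1.76 to 4.24; permutation test, adjusted p = 0.00360). The membrane skeleton genes Epb41 and Sptb had 29 and 26, Hemgn 23, Bcl11a 21, Nfe2 15 and Tal1 13. The embryonic globin genes Hbb-y and Hbb-bh1 had 27 each, largely the same peaks, since neighbouring genes share a region. With each distal peak counted 1 time in a list, an alternative chosen after the data were seen, the erythroid genes had 331 distal peaks, or 8.71 per gene, against 2.82 in random lists (95% range 1.76 to 4.21; permutation test, adjusted p = 0.0180). The erythroid list was the only one of 18 past the threshold, and it stayed past it in all 8 alternatives. The other lists lay between 0.600 in lymphoid genes (adjusted p = 0.454) and 4.78 in heme synthesis genes (0.454) by the permutation test. Fetal hepatocyte genes had 2.28 (adjusted permutation p = 0.664), progenitor genes 3.52 (0.664), housekeeping genes 4.03 (0.454) and proliferation genes 3.97 (0.454). Of the 17416 distal peaks, 60.9% had their summit in an intron, 31.03% between genes and 8.04% in an exon, against 42.1%, 54.6% and 3.27% for random placement.

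The globin regions showed this directly. From 50 kb before the first to 50 kb after the last beta-globin gene, on chromosome 7 from 103762524 to 103903216, there were 37 replicated peaks, of which 27 were distal. The highest, with a fold of 17.8 (8.48 in replicate 1 and 17.4 in replicate 2), lay between genes from 103858477 to 103859265, with its summit 5764 bp from the start of the embryonic gene Hbb-y. The adult gene Hbb-bt had a promoter peak of 16.0 and Hbb-bs of 7.90, and the embryonic genes Hbb-y and Hbb-bh1 had 4.93 and 4.29. The summit of the Hbb-bt peak lay 1726 bp from the start, outside the promoter that the peak overlaps. Those of Hbb-bs, Hbb-y and Hbb-bh1 lay at 511, 129 and 43 bp, so the folds are not all of signal at the start. The alpha-globin region, on chromosome 11 from 32175628 to 32347298, held 47 peaks, of which 29 were at promoters, with the highest at Nprl3 (43.8). The promoters of Hba-a1 (13.4) and Hba-a2 (16.9) are near-copies of each other. Of the 50-base words at the promoters of Hbb-bt and Hbb-bs, 40.8% and 34.0% occur elsewhere too, so the values of these 4 genes are uncertain. The summits of the peaks of Hba-a1 and Hba-a2 also lay outside the promoters, 2173 and 2358 bp from the starts. Around Runx1, on chromosome 16 from 92551466 to 92876149, there were 18 peaks, with 30.3 at the proximal start, 17.9 at the distal start and 16 distal peaks. Gata1 had 10 peaks in its region (highest 19.3) and Kit 3 (highest 10.2). The region of Hnf4a held 5, the highest of them at the neighbour Ttpal (34.2). The fetal RNA-binding protein gene Lin28b had 6 (highest 22.6), and the Igf2 to H19 region 16, with 6.93 at the start of Igf2 and 8.44 in H19. The Hoxa region held 17 peaks, none above 6.97.

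**Figure D4:**
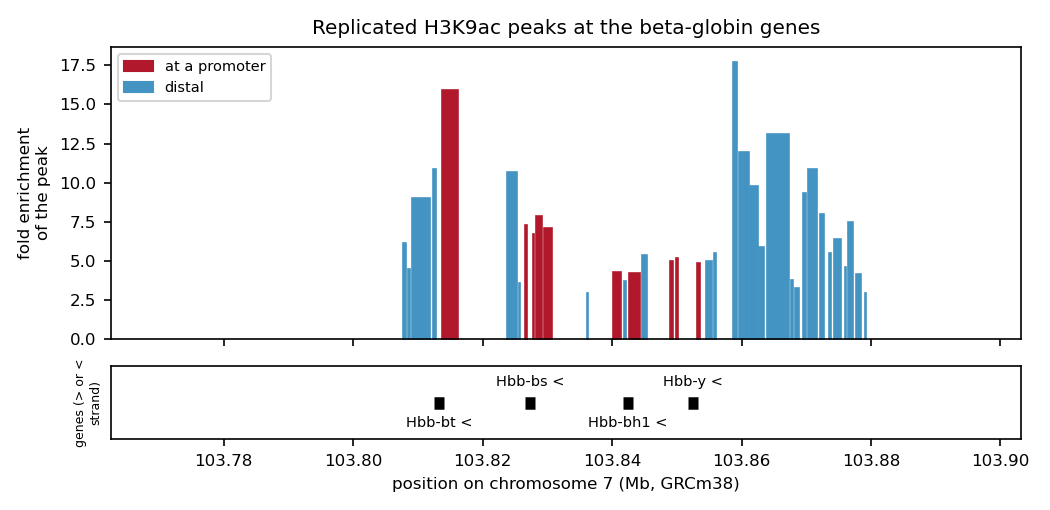
Replicated peaks around the beta-globin genes by position on chromosome 7 (horizontal axis, Mb) and fold enrichment over control (vertical axis), with the genes and their strand underneath. Blue peaks are distal and red peaks lie at a promoter, and the highest distal peak reaches 17.8 beyond Hbb-y.

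Sequence motifs at distal peak summits were compared with flanking sequence, to see which transcription factor sites the distal peaks hold. The consensus of GATA factors, WGATAR, the site bound by GATA1 in red cell precursors, was present within 100 bp of 26.1% of summits and in 29.6% of windows 2 kb away that touched no peak (14948 pairs, exact McNemar test, two-sided, adjusted p = 4.49e-11 over 21 motifs). The same sequence read backwards, a control of equal composition, was at 19.5% of summits and 25.3% of flanks (adjusted exact p = 2.72e-33). The KLF consensus was more frequent at summits, with 10.7% against 6.58% (adjusted exact p = 1.45e-36), as was its reversed control, with 9.45% against 5.004% (1.36e-49). Both of these sequences can hold CCCACCC, so the reversed sequence is no clean control for KLF. The ETS consensus was at 6.34% against 5.39% (adjusted exact p = 0.00102) and the CEBP consensus at 12.3% against 14.6% (1.25e-08). Their reversed controls moved the same way, with 8.57% against 7.27% for ETS (adjusted exact p = 9.53e-05) and 11.02% against 15.1% for CEBP (3.02e-25). The motifs of RUNX (9.57% against 9.26%, adjusted exact p = 0.602), NFE2/AP-1 (3.53% against 3.43%, 0.864), FOXA (2.65% against 2.78%, 0.781), HNF4 (0.274% against 0.234%, 0.793), HNF1 (0.127% against 0.114%, 0.930) and MEF2 (0.301% against 0.281%, 0.930) did not differ past the threshold, and the neurogenic E-box was less frequent (4.60% against 5.50%, 0.000969). The direction for GATA depended on the windows. It was 1.31 percentage points more frequent at summits against windows of like GC content (adjusted exact p = 0.0193) and 3.197 points more frequent against flanks with windows of 250 bp either side (9.65e-08, range 9.18e-13 to 0.0193), while its reversed control stayed less frequent in both. Against windows of like GC content RUNX was more frequent, with 9.61% against 7.84% (adjusted exact p = 1.24e-07, range 1.24e-07 to 0.703), and its reversed control differed by -0.783 points with flanks (0.0325) and by -0.660 points here (0.0620). NFE2/AP-1 was more frequent with windows of 250 bp (adjusted exact p = 0.00263) and with replicate 2's list (0.00104), and HNF4 with replicate 1's list (0.0315). The call of the E-box was lost with windows of like GC content (adjusted exact p = 0.176) and with replicate 1's list (0.111). In all, 4 motifs and controls were more and 8 less frequent at summits with flanks, and 5 and 1 with windows of like GC content.

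The X chromosome was compared with the autosomes because the pools held embryos of both sexes. Of 948 protein-coding genes on the X, 361 had a promoter peak (38.1%), and of 20807 on the autosomes, 12428 (59.7%), a difference of -21.6 percentage points (Fisher's exact test, two-sided, p = 3.01e-39). X-linked genes with a peak included the erythroid genes Alas2, the first enzyme of heme synthesis in red cells (24.7), and Gata1 (19.3). Their median fold was 12.1, and that of covered autosomal genes 19.5. Promoters on the X had a median CpG ratio of 0.334, against 0.486 on the autosomes, and 18.7% of them were mostly repeated sequence, against 4.18%. The difference was -11.6 points against autosomal genes of like CpG ratio and -8.30 points with repeated promoters left out as well, and in both p was 0.0002, the smallest the permutations can give.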

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

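The test of a low share of hepatocytes was chosen, and its prediction for the neural and muscle lists added, after its result was seen, the tests of the X chromosome by CpG ratio and by repeated promoters were added after the main difference had been seen, and the test of both together was set after each alone had been seen.

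The list of replicated peaks had 8 peaks on 4 unplaced or unlocalized sequences, which were not used for any gene result, with a median fold of 4.03 and a highest of 14.4. They are given because they lie outside every comparison. No expected number for these sequences was computed, so their count has no reading here.

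Fetal hepatocyte promoters with a peak had a median fold of 5.58, against 19.2 in random lists. A low CpG ratio at the most upstream starts of these genes was argued against. The median stayed below that of CpG-matched lists (15.1, 95% range 8.47 to 22.0, permutation p = 0.0006). Other starts of these genes were not matched. A small share of hepatocytes among the cells may lower the fold of their genes. All 4 lists of cells thought to be a minority (fetal hepatocyte, endothelial, myeloid and mesenchymal) lay below their CpG-matched range, but so did the neural and muscle lists, so low activity of the genes and a small share of cells cannot be told apart here. The share of cells was weighed as a matter of mixed tissue, and apart from it no biological explanation was tested, since the design holds 1 group.

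Fewer X-linked than autosomal genes had a promoter peak, by -21.6 percentage points. Low CpG content at the most upstream start could account for part of this but not for all. The difference was -11.6 points against autosomal genes of like CpG ratio. Repeated promoters, where reads may not be placed, left -15.5 points when removed. Both settings describe a gene's most upstream start alone, so its other starts were not weighed. With both settings at the same time -8.30 points were left, and the X-linked share of 46.6% lay below the 95% range of 52.1 to 57.6% of the matched draws. Gene families of the X expressed in other tissues stay open as an untested explanation. The number of X copies in pools of both sexes was not tested either, so the remaining -8.30 points cannot be read as gene content alone. Covered X-linked genes also had a lower median fold, 12.1 against 19.5 in covered autosomal genes, with neither setting applied.

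Slc25a37 was the only erythroid gene of 39 without a promoter peak. A candidate explanation is that reads cannot be placed there. At the gene's most upstream start, 100% of the 50-base words of the promoter occur more than 1 time in the assembled genome. Mostly repeated promoters had a peak in 4.12% of 1215 genes, against 61.5% of 20723 others, and within the upper 50% of genes by CpG ratio in 19.7% against 89.5% (Fisher's exact test, p = 3.83e-79). The rule has exceptions, since Hba-a1 and Hba-a2, with 69.1% and 74.6% of repeated words, had peaks. A lack of the mark at Slc25a37 was not tested, because the lists hold no value where no peak was called.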

How the results depend on the processing

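The basic transcript set, the nearest start alone, the length matching of distal peaks, the counting of each distal peak 1 time and the CpG and repeat settings of the X chromosome were chosen after the data were seen, as was the rule that a difference of exactly 0 has no direction. Each setting gave 2 counts of calls, 1 for each direction. These counts stayed within 1.5 times the main count in 19 of 20 cases for presence, 8 of 8 for fold, 9 of 10 for width, 16 of 16 for distal peaks, 18 of 18 for pairs and 8 of 10 for motifs. Single lists, pairs and motifs kept direction and side of the threshold in 200 of 220, 66 of 72, 79 of 90, 139 of 144 and 65 of 72, and for motifs 70 kept both and 22 turned. The X chromosome difference kept its call in all 6 settings, and the distal peaks of erythroid genes in all 8. Except where the construction shows it (a longer or shorter list, a wider promoter), the cause was not tested. Depth is unknown, so how far it limits the lists could not be told, and the low overlap at low fold bears on the smallest peaks. No paired analysis was possible because there is 1 group.

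Overlap of replicate 1 peaks was 54.9% with 50% of the length required, 68.6% at −log10 q of at least 2 and 59.7% with equal list lengths, and that of replicate 2 peaks was 36.6%, 55.3% and 53.5%. Spearman's rho was 0.872 with −log10 p. The share of peaks at promoters was 63.2% with promoters of 2.5 kb, 35.1% with the jointly called list, 46.4% with the basic transcript set and 34.2 to 40.3% with single replicates. The share of genes was 63.0% with the jointly called list and 60.0 to 62.0% with single replicates. With the jointly called list 8 lists stood above other genes. With single replicates 5 to 8 lists were narrower than random.

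Lists and pairs that turned had no call before or after. In percentage points, mesenchymal presence was 3.72 with the jointly called list and 0.00365 to 11.3 with single replicates, coagulation was 17.2 against CpG-matched lists, and myeloid minus lymphoid was -10.0 to 16.7 with single replicates. Width in bp against random was 73 for lymphoid genes with CpG matching, 47.5 for fetal hepatocyte genes with a joining gap of 3 kb, and, with single replicates, -278 to -236.5 for mesenchymal and -189 to 144 for imprinted genes. Distal peaks against random were 0.455 for endothelial and 0.176 for mesenchymal genes at 20 kb, 0.235 for mesenchymal genes with matched neighbouring starts, and, with single replicates, -0.769 to 0.308 for endothelial and -0.778 to 0.571 for muscle genes.

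Motifs turned most. The number less frequent at summits was 1 with windows of like GC content and 5 with windows of 250 bp. In percentage points, windows of like GC content gave 1.31 for GATA, 0.391 for FOXA, 0.660 for CEBP, and for reversed controls 0.368 (NFE2/AP-1), -0.431 (ETS), 0.419 (FOXA), 0.327 (CEBP) and 0.126 (E-box). Windows of 250 bp gave 3.197 for GATA, -0.611 for RUNX, 0.467 for FOXA, -0.0431 for HNF1 and 0.0431 for the reversed E-box. Single replicates gave -0.271 to -0.203 for RUNX, -0.0504 to -0.0273 for HNF1, -0.0210 to -0.0121 for MEF2, 0.0819 to 0.132 for reversed NFE2/AP-1 and -0.0147 to 0.109 for the reversed E-box. GATA was thus less frequent at summits than in flanks with windows of 100 bp only, and more frequent with those of 250 bp and against windows of like GC content. RUNX was 1.77 percentage points more frequent against windows of like GC content.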

Other observations

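The comparison of motifs with their reversed sequences, and the genes named here, were chosen after the data were seen.

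Genes that make no protein were among those with the strongest mark. Among those ranked here, the highest promoter fold was 66.7, at the processed transcript 1810026B05Rik on chromosome 7 (peak from 73555930 to 73558631). Next in this ranking was Dleu2, the host of a microRNA cluster that restrains cell division (52.6). The microRNA gene Mirlet7i had 43.3. The nuclear long noncoding RNA gene Malat1 had 42.5, and its peak ran from 5795664 to 5804880 on chromosome 19. No antisense RNA gene was among those ranked, although 907 had a promoter peak. Genes left out may thus have higher folds. Mir17hg, the host of a microRNA cluster that promotes growth, had 37.1, and the snoRNA host gene Snhg6 36.3. Several of these peaks also cover the start of another gene that makes no protein.

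Genes with many distal peaks in their body or within 50 kb were of several kinds, and no test of their functions was made. The kinase gene Hipk2 had 46, and Tbxas1 beside it 42. Ccnd3, whose cyclin acts in the divisions of red cell precursors, had 32 and a promoter fold of 41.1, and the lipin gene Lpin2 also had 32, with 49.7. The lipid kinase gene Pip4k2a had 31 and Epb41, of the red cell membrane skeleton, 29. The collagen gene Col5a1 and the deubiquitinase gene Usp7 also had 32, and Rere and Rreb1 had 29 each. In the histone cluster on chromosome 13, Hist1h3e and Hist1h4f each had 29 in a searched region of 100 kb. Gm20388 had 174, but its annotated body makes the searched region 4485 kb long, Fgfr2 had 30 in 3055 kb, and Gse1 had 58 in 443 kb.

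The reversed sequences allowed 1 further view of the motifs, since a sequence and its reverse have the same composition. The odds of the forward over the reversed sequence were compared between summits and flanks by Fisher's exact test, two-sided, adjusted over 10 motifs. That test took summits and flanks as independent and ignored their pairing, so its p-values are approximate. GATA was favoured at summits (odds ratio 1.25, adjusted exact p = 1.07e-05), as were CEBP (1.19, 0.00292), RUNX (1.14, 0.0417) and HNF1 (5.01, 0.00881, from few windows, with 17 forward and 8 reversed at summits and 14 and 33 in flanks). For GATA, CEBP and HNF1 the odds rose mainly because the reversed sequence was rarer at summits. Windows with the forward sequence alone numbered 2414 at summits and 2462 in flanks for GATA and 1561 and 1759 for CEBP, and those with the reversed alone 1427 and 1818, and 1365 and 1827. The odds were compared with flanks only. Against windows of like GC content CEBP (0.660 percentage points, exact McNemar test, adjusted p = 0.101) and its reversed control (0.327, 0.391) both fell short of the threshold. KLF had an odds ratio of 0.781 (Fisher's exact test, adjusted p = 0.0243), but both its consensus and the reversed sequence can hold CCCACCC. The reversed sequence is thus no clean control for KLF, and no preference can be read from this value. FOXA had 1.21 (0.0778), HNF4 1.17 (0.803), NFE2/AP-1 1.06 (0.644), ETS 0.994 (0.947) and the neurogenic E-box 0.869 (0.290). By contrast, the plain shares of GATA and CEBP within 100 bp were lower at summits than in flanks, while with windows of 250 bp that of GATA was higher by 3.197 percentage points.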
